A study of Mus musculus with 15 samples.

How the data were processed

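Regulatory T cells (Tregs), T cells that carry the transcription factor Foxp3 and restrain immune responses, were sorted from adult mice through a Foxp3 reporter, and their messenger RNA was sequenced in bulk. Per the labels' protocols, the mice were of the line named RelB-dDC or littermate controls on the C57BL/6 background. The labels do not spell the line's name out; it is read here as mice that lack RelB, a subunit of NF-kappaB, in dendritic cells, and the shorter name dDC is used throughout. RelB in the sorted Tregs is not the target of that deletion, so the Relb count does not check the genotype labels.

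Per the labels' protocols, RNA was isolated with the RNeasy Micro Kit, and cDNA was made with SmartScribe reverse transcriptase from a poly-dT primer with a template switching oligonucleotide and amplified for 12 cycles. The cDNA was sheared by ultrasound, and libraries were made with NEBnext Ultra DNA chemistry and amplified for 15 cycles. This chemistry does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart. No molecular identifiers are named, so reads are not independent molecules, and the floors given for values of 0 cover counting error only. Per the submitters' processing notes, the tools were bcl2fastq 2.19.1, GSNAP in version 2018-03-11 (an aligner) and featureCounts 1.6.0 (a read counter) with the mouse genome build mm10. The strand setting, the treatment of reads that match several places and any trimming are not given in the sources used here.

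The authors deposited 1 table of raw counts, whole numbers of reads per gene and library, with the Ensembl identifier, chromosome, start, end and strand of each gene. Each of the 15 libraries was assigned to its group through its own label. The table holds 45798 features, of which 92 are spike-in sequences. These received at most 6 reads in a library, or 3.2e-05 percent of its counts, and were left out of all tests. Symbols came from a table of GENCODE M21 names and were found for 45143 of the 45706 gene identifiers (98.8 percent), which hold 99.93 percent of the reads. Coordinates are those of the deposited table in mm10, counted from 1.

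Total counts lay between 15714286 and 24332044 per library. Genes with enough counts were kept with filterByExpr in edgeR 4.0.16 (R 4.3.3) on the 6 groups of tissue and genotype, which left 18423 genes with 99.93 percent of the counts. Library sizes were scaled with TMM factors, and 1 quasi-likelihood model with robust moderation was fitted to all libraries with a mean for each group and 9 residual degrees of freedom. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05; every adjusted p for a gene is from edgeR unless another tool is named. The median biological coefficient of variation was 0.55 over the tested genes, 0.18 for genes above 100 CPM (counts scaled to a common library total) and 1.29 for genes below 5 CPM, so small differences of weakly expressed genes could not be resolved. Group values are TMM-scaled CPM as mean ± SD. A fold against a group with no count is a lower bound computed against 3 counts per library.

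The comparisons were dDC against control within spleen, thymus and peritoneal cavity, the average of these 3 differences with equal weight, the differences between them, and peritoneal cavity or thymus against spleen in controls. In addition, 31 gene lists with 475 genes were fixed, 17 of T cell programs and 12 of markers of other cell types; 432 of the genes were tested, and 28 lists had at least 5 tested members and were tested as sets. The set test was camera in limma 3.58.1 on voom log2 CPM with a preset correlation between genes of 0.01, beside camera with an estimated correlation and fry, and p was adjusted over the lists of a comparison. Unless a correlation is named, the adjusted p of a list is that of camera with the preset value. Members of a list were counted with p adjusted over all genes and adjusted over the list alone. A list score, the mean log2 CPM of its members with a prior count of 2, was compared by an exact two-sided permutation of genotype labels within tissues, with 1200 relabellings.

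The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Among genes past the threshold in a dDC comparison, the rule named the 12 largest changes in each direction with a mean of at least 5 CPM in the higher group and group ranges that did not overlap, or for the average the same sign in all 3 tissues. For tissue comparisons it named 8 in each direction. Where fewer than 6 genes passed, the 3 with the smallest p in each direction are given as values. For each list it took up to 4 members past the threshold, or for a program up to 2 with the smallest p as values. Foxp3, Relb, Il2ra, Ikzf2, Il1rl1, Klrg1 and Gata3 were always taken. Xist, Tsix, Y-linked genes, antigen receptor segments, mitochondrial and ribosomal protein genes and genes with only a clone or model name were left out of naming.

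Alternatives were median-of-ratios size factors, DESeq2 1.42.0, limma-voom with sample weights, no count filter, a filter of 5 CPM in 2 libraries, removal of receptor segments with mitochondrial and sex-linked genes, no robust moderation, a fit of the compared groups alone, and each library left out in turn. For the overlap between tissues they were an adjusted p under 0.1 and an unadjusted p under 0.01. A term for sex was planned and not run because all libraries came from males by their Y-linked counts. The average over spleen and thymus alone, a block for neighbouring library numbers, the permutation of list scores and the left-out libraries for lists were added after the data were seen.

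The tests were also run on simulated data with 200 changed genes, 50 at each of 4 fold sizes, among the 18423 genes, drawn from those with a mean of at least 5 CPM. For the average comparison edgeR recovered 10 percent of genes changed 1.5-fold, 44 percent at 2-fold, 74 percent at 4-fold and 94 percent at 8-fold, and 0.893 percent of its calls were false. At 2-fold it recovered 16 percent in the spleen design, 6 percent in the thymus design and 6 percent in the peritoneal design. DESeq2 called more genes, but 37.2 percent of its calls were false in the simulated average and 56.8 percent in the simulated peritoneal comparison. The simulated counts were drawn with dispersions estimated by edgeR, which may favour edgeR.

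Replicate libraries were checked for copies, and none was found, since the chi-square per degree of freedom between 2 libraries of a group lay between 47.3 and 110.5. The labels do not say that libraries of a group came from separate animals, so p measures the spread between these samples, which may be technical. They also do not say whether libraries of different tissues came from the same mice. The average, the exact permutation and the correlation between tissues treat the tissues as independent. If mice were shared, their p could be too small. Of the 158 named genes, 37 have an exon that overlaps another gene, and for 9 the overlapping gene holds over 10 percent as many reads: Bid, Ebi3, Fdft1, Foxp3, Irf7, Nfkbib, Oasl1, Rhoq and Stat5a. Their values are uncertain, as are those of genes with near-identical copies, namely Krt83, Ly6c1, Apol9b, Lilra6, Bcl2a1b and the globins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.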

Results

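Foxp3-positive Tregs from spleen, thymus and peritoneal cavity of dDC mice and littermate controls were compared in 15 libraries, 8 from controls and 7 from dDC mice. Spleen had 3 control and 3 dDC libraries, thymus 3 and 2, and peritoneal cavity 2 and 2, with 15714286 to 24332044 counts each. Tissue dominated the data: the first 2 principal components held 38.8 and 15.3 percent of the variance of the 500 most variable genes. Foxp3, the factor that defines Tregs, was present in every group, at 205.1 ± 25.31 CPM in spleen controls, 274.5 ± 52.43 in thymus controls and 287.3 ± 46.36 in peritoneal controls. Markers of other cells were present too. The mean of the B cell list was 320.02 and 1176.06 CPM in peritoneal controls 1 and 2, between 112.55 and 328.13 CPM in the 6 spleen libraries, and between 12.9 and 23.86 CPM in the 5 thymus libraries.

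**Figure D1:**
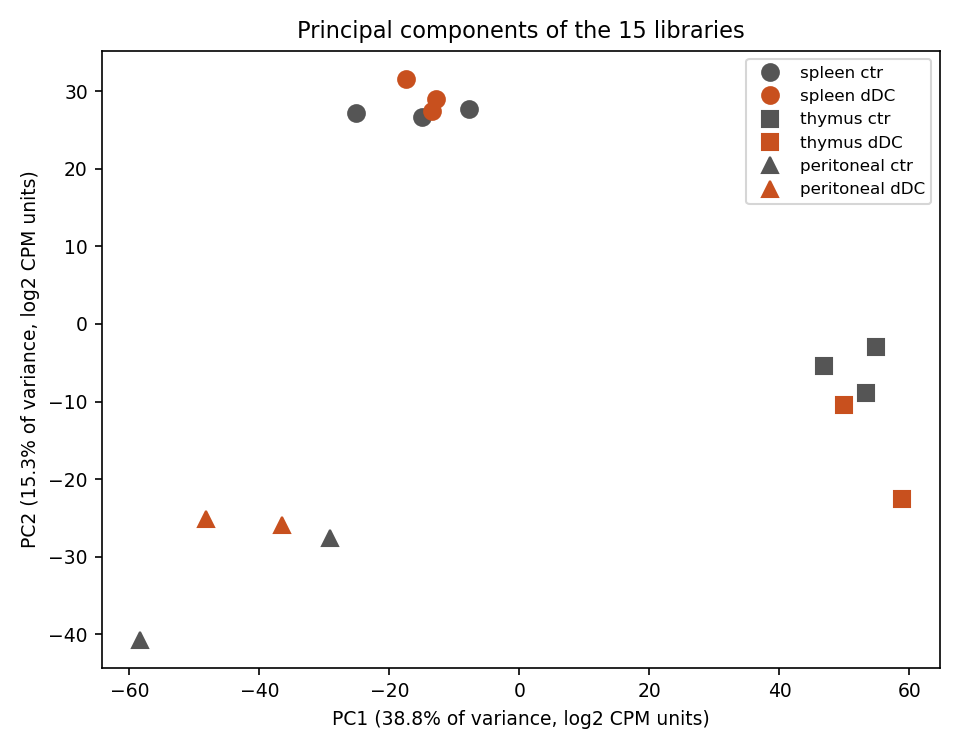
Principal components of the 15 libraries from log2 CPM, with 1 point per library, shapes for tissue and colours for genotype. Component 1 (38.8 percent) and component 2 (15.3 percent) set the 3 tissues apart.

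**Figure D2:**
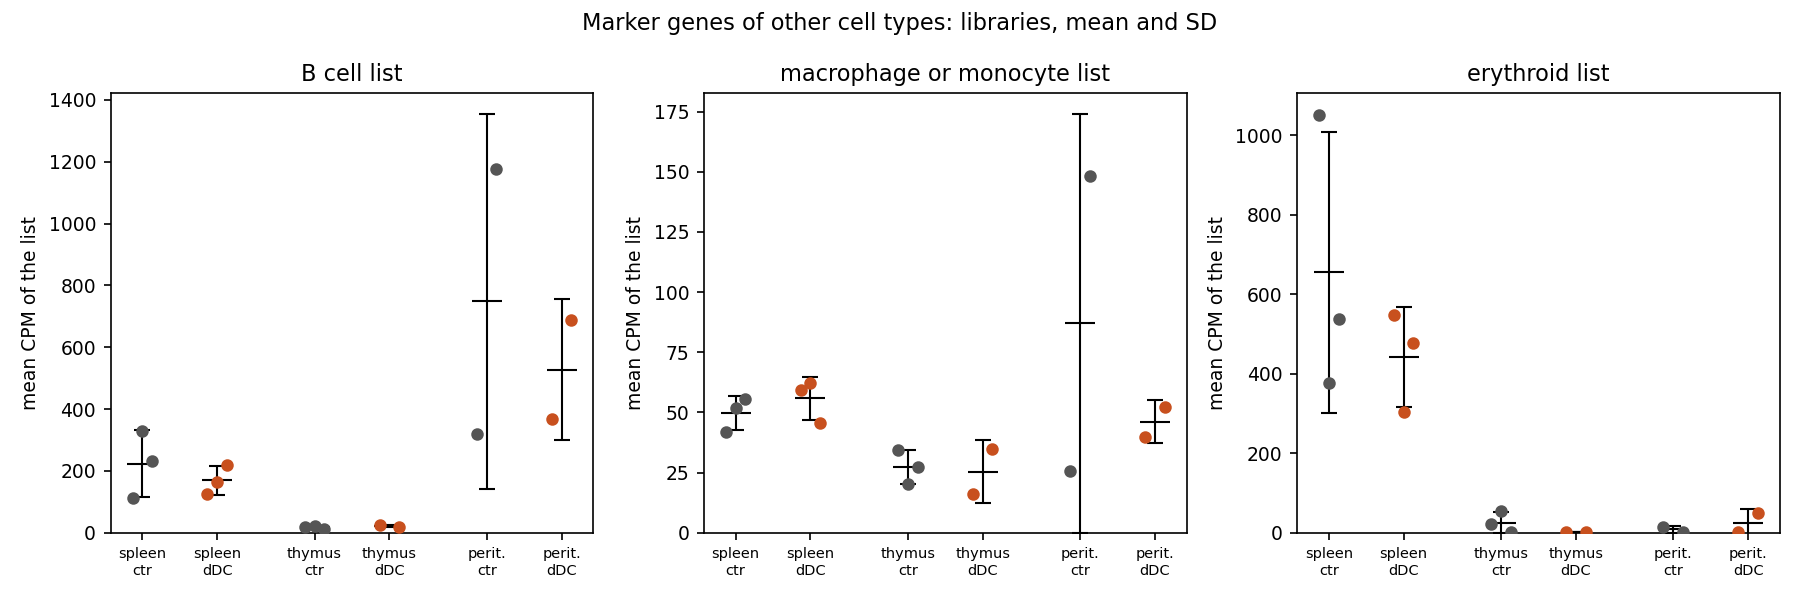
Mean CPM of the B cell, macrophage and erythroid marker lists in each library (points) with group mean and SD, by tissue and genotype. Peritoneal control 2 had the highest B cell value (1176.06 CPM) and macrophage value (148.41 CPM).

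Across the 3 tissues, Tregs of dDC mice carried more RNA of 2 surface receptors, the adhesion receptor Itgb1 (integrin beta 1) and the semaphorin and VEGF co-receptor Nrp1, a known marker of Tregs made in the thymus. They also carried more of Fam129a, a stress response gene, of the calcium-binding protein gene S100a11 and of the actin-binding protein gene Tagln2. Bcl2, which protects cells from death, and Actn1, which crosslinks actin, were lower. So were the transcription factor gene Gtf2i and Arhgap15, whose product restrains the GTPase Rac. Of the genes named here, only Itgb1, Nrp1 and Fam129a also passed in the average of spleen and thymus alone. The calls of the others were lost without some single libraries. In the fixed lists, genes of tissue Tregs and effector Tregs moved up and genes of naive or resting T cells moved down.

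Averaged over the tissues, 14 genes passed the threshold with edgeR, 9 higher and 5 lower in dDC, beside 1715 genes at an unadjusted p under 0.05 where chance gives 921. With limma 19 genes passed and with DESeq2 384. Itgb1 (ENSMUSG00000025809, chromosome 8, 128685654 to 128733200) rose 2.05-fold (log2 1.03, SE 0.09, adjusted p = 0.0015), and Nrp1 (ENSMUSG00000025810, chromosome 8, 128359073 to 128505462) rose 1.53-fold (log2 0.62, SE 0.06, adjusted p = 0.00293). Fam129a (ENSMUSG00000026483, chromosome 1, 151571186 to 151721939) rose 1.71-fold with an adjusted p of 0.00719. Sh3bgrl (ENSMUSG00000031246, chromosome X, 109095365 to 109197873), for a small thioredoxin-like protein, rose 1.7-fold with the same adjusted p. S100a11 rose by 0.72, Plekhb2, an endosome gene, by 0.72 and Tagln2 by 0.56 on the log2 scale (edgeR adjusted p = 0.0132, 0.0466 and 0.0274). The hair keratin gene Krt83 had a log2 value of 3.62 (adjusted p = 0.00891) that rests on peritoneal controls with no count. Bcl2 (ENSMUSG00000057329, chromosome 1, 106538178 to 106714274) fell (log2 -1.03), as did Actn1 (-0.93), Gtf2i (-0.79) and Arhgap15 (-0.69) (edgeR adjusted p = 0.0467, 0.0466, 0.0157 and 0.0467). The remaining 2 have only model names, Gm12854 (0.74) and Gm15708 (-1.53). For all 14 genes, 7 of 7 dDC libraries lay on the called side of the control mean of their tissue. Group ranges were separate in 3 of 3 tissues except for Krt83, Plekhb2 and Gm15708 (2 of 3). The genes were called on these same libraries, so this is no separate evidence. Of all tested genes, 10.1 percent had separate ranges in spleen, 19.4 percent in thymus and 34.1 percent in the peritoneal cavity.

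In CPM, Itgb1 went from 186 ± 34.97 to 350 ± 6.078 in spleen, from 143.3 ± 14.87 to 322.8 ± 9.517 in thymus and from 324.9 ± 27.17 to 658.5 ± 89.82 in the peritoneal cavity. Nrp1 went from 752.5 ± 61.8 to 1244 ± 84.38, from 997.8 ± 48.72 to 1323 ± 117.6 and from 703.5 ± 20.26 to 1160 ± 133.9. Bcl2 went from 301.2 ± 90.49 to 136.7 ± 9.859, from 401.8 ± 128.8 to 254.7 ± 44.8 and from 435.6 ± 48.08 to 177.9 ± 13.93. Actn1 went from 196.1 ± 29.32 to 155.6 ± 15.43, from 207.2 ± 11.62 to 119.2 ± 58.44 and from 170.9 ± 17.53 to 53.83 ± 5.576. Several Treg genes did not pass the threshold: Foxp3 (average log2 -0.05, adjusted p = 0.984), Relb (-0.14, 0.936), Il2ra (-0.26, 0.491), Ikzf2 (0.12, 0.665), Gata3 (0.51, 0.303), Klrg1 (0.97, 0.0875) and Il1rl1, the receptor for interleukin 33 (1.51, 0.131), all by edgeR.

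**Figure D3:**
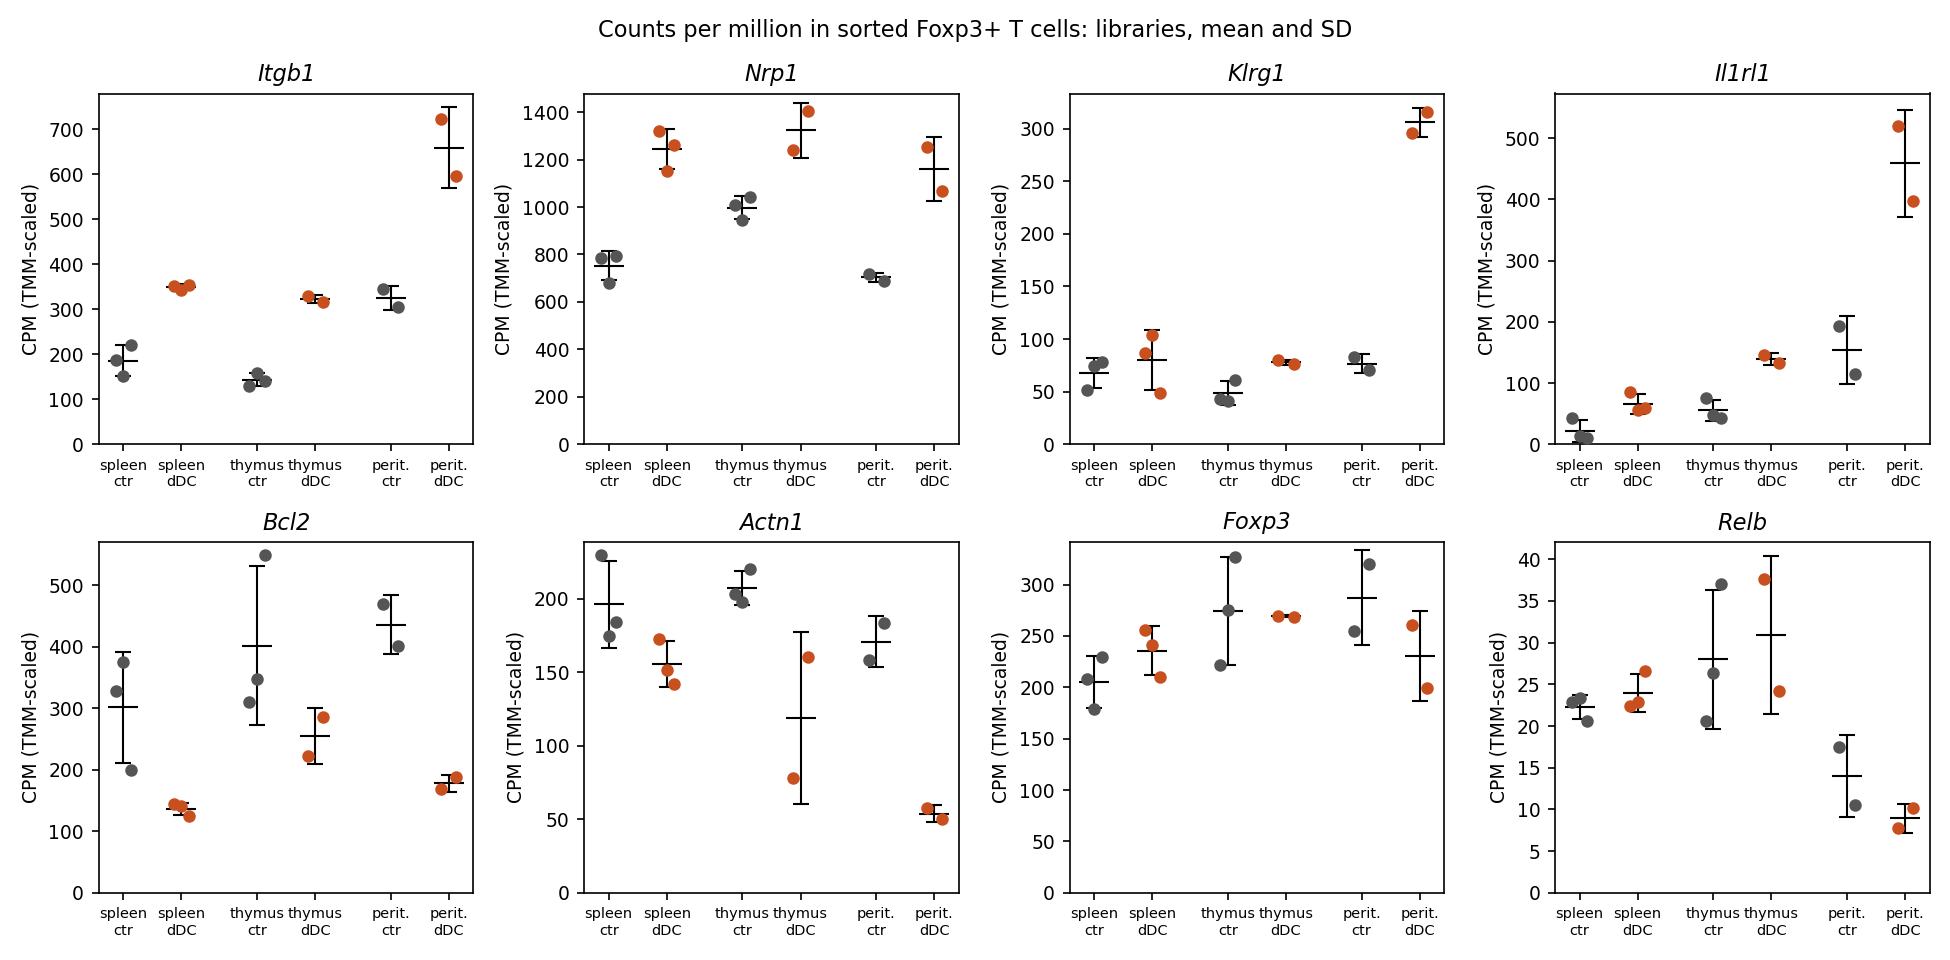
TMM-scaled CPM of 8 genes in each library (points) with group mean and SD, for controls and dDC mice in the 3 tissues. Itgb1 and Nrp1 were higher and Bcl2 lower in dDC when averaged over tissues, while Foxp3 and Relb did not pass the threshold.

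The call depended on single libraries. The count of 14 became 123 without peritoneal control 1, 44 without thymus dDC 2, 5 without peritoneal dDC 2, 6 without spleen dDC 1, 7 without peritoneal control 2, 8 without spleen control 2, 8 without spleen dDC 2, 9 without thymus control 2 and 9 without thymus control 3. Itgb1, Nrp1, Fam129a, Sh3bgrl and Krt83 passed with each of the 15 libraries left out (highest edgeR adjusted p = 0.0151, 0.0151, 0.0294, 0.0393 and 0.0393). In the average of spleen and thymus alone Sh3bgrl (0.65, adjusted p = 0.167) and Krt83 (0.61, adjusted p = 0.721) were lost, and Krt83 was also lost with limma. With neighbouring library numbers as a block, none of the 12 named genes passed. Itgb1, Nrp1 and Fam129a then had edgeR adjusted p of 0.0929, 0.117 and 0.151. The block leaves fewer residual degrees of freedom than the 9 of the main fit. The lost calls therefore cannot tell an effect of the block from lower power. S100a11 was lost without 2 libraries, peritoneal control 2 (0.0621) and peritoneal dDC 2 (0.0815). Gtf2i was lost without 4, namely spleen dDC 1 (0.0585), peritoneal control 2 (0.0621), peritoneal dDC 2 (0.107) and thymus dDC 1 (0.0646). Tagln2, Bcl2, Plekhb2, Actn1 and Arhgap15 were lost without 9, 11, 11, 12 and 12 libraries, with the highest adjusted p (0.157, 0.18, 0.179, 0.199 and 0.169) without peritoneal dDC 2. Of the 12 named genes, those kept were 12 and 5 without peritoneal controls 1 and 2, and 9 and 5 without peritoneal dDC 1 and 2. They were 7, 7 and 10 without spleen controls 1, 2 and 3, and 6, 7 and 7 without spleen dDC 1, 2 and 3. For the thymus they were 10, 7 and 7 without thymus controls 1, 2 and 3, and 9 and 11 without thymus dDC 1 and 2.

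Of the 28 lists, 7 passed in the average, 3 of them also with an estimated correlation and 7 with fry; the lowest adjusted p of the others was 0.059. The tissue Treg list, genes of the interleukin 33 responsive Tregs of non-lymphoid organs, moved up (adjusted p = 2.18e-12; adjusted p = 0.00491 with an estimated correlation). Its median log2 value was 0.67, or 0.58 with genes at the floor, and 21 of 22 members were positive. Adjusted over the list alone 11 members rose, among them Il1rl1 (1.51), Klrg1 (0.97), Rora (0.74) and Gata3 (0.51), and over all genes 0 did. The effector Treg list moved up too (adjusted p = 1.1e-09; adjusted p = 0.0395 with an estimated correlation; median 0.37). In it 11 of 28 members rose adjusted over the list alone, among them Icos (0.61), S100a4 (1.08), Fgl2 (1.33) and Ebi3 (1.24), against 1 over all genes, Itgb1. The naive or resting list moved down (adjusted p = 4.79e-14; adjusted p = 0.0465 with an estimated correlation; median -0.51). Adjusted over the list alone 12 of its 22 members fell, among them the chemokine receptor gene Ccr7 (-0.55) and the transcription factor genes Bach2 (-0.77) and Satb1 (-1.21), and 1 rose, Il7r (0.40); over all genes 2 fell. By exact permutation of the list scores, 7 of 7 dDC libraries lay above the control mean of their tissue for the tissue Treg list (exact p = 0.00167, adjusted 0.0233), 0 of 7 for the naive list (exact p = 0.0025, adjusted 0.0233) and 6 of 7 for the effector list (exact p = 0.0125, adjusted 0.0875). These 3 lists passed with each of the 15 libraries left out (highest adjusted p = 1.03e-09, 1.18e-05 and 2.65e-11 for tissue, effector and naive), and the members called over the list alone then numbered 9 to 12, 10 to 12 and 11 to 16. These fits with a library left out used only the preset correlation of 0.01. With all libraries the estimated correlation was 0.036, 0.081 and 0.221 for tissue, effector and naive. Camera with an estimated correlation was not run with libraries left out. Of marker lists for other cells, none passed in the average with camera: the B cell list had a median of -0.57, or -0.28 at the floor (adjusted p = 0.61). The erythroid list had a median of -1.85, or -1.48 at the floor, with 0 of 8 positive (0.167), and the stromal list had -1.52 with 0 of 6 positive (0.23).

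The Treg identity list, core Treg genes, moved up (adjusted p = 0.000122; adjusted p = 0.0873 with an estimated correlation). Adjusted over the list alone 6 of 22 members rose, including the costimulatory receptor genes Tnfrsf4 (0.44) and Tnfrsf18 (0.36) and the integrin gene Itgae (1.48), and Gpr83 fell (-1.31); over all genes 1 rose, Nrp1. By exact permutation it did not pass (6 of 7 dDC libraries above the control mean, exact p = 0.04, adjusted 0.224). The chemokine receptor list moved up (adjusted p = 0.0117; adjusted p = 0.0873 with an estimated correlation), with 5 of 20 members higher adjusted over the list alone, such as Cxcr4 (1.02) and Ccr4 (0.89), 1 lower, Ccr7, and 0 over all genes. It was lost without thymus dDC 2 (0.163) and by exact permutation (4 of 7 above, exact p = 0.108, adjusted 0.504). The type 2 helper list moved up (adjusted p = 0.0386; adjusted p = 0.113 with an estimated correlation), with 4 of 10 members higher and 2 lower adjusted over the list alone and 0 over all genes. Of the 4 higher, 3 (Il1rl1, Gata3 and Ccr8) are also in the tissue Treg list. Its call was lost without peritoneal control 1, peritoneal control 2, peritoneal dDC 2, thymus control 2 or thymus dDC 1 (highest adjusted p = 0.0738). By exact permutation it passed (7 of 7 above, exact p = 0.0025, adjusted 0.0233). The 2 lower members became 1 without each of 11 libraries, that is all but spleen dDC 1, peritoneal control 1, thymus control 2 and thymus dDC 2. The glycolysis list moved up by a median of 0.13 (adjusted p = 0.0173; adjusted p = 0.245 with an estimated correlation), with 1 member higher adjusted over the list alone, Aldoa (0.30), and 0 over all genes. It was lost without peritoneal control 1, peritoneal dDC 1 or thymus dDC 2 (highest adjusted p = 0.121) and by exact permutation (5 of 7 above, exact p = 0.352, adjusted 0.616).

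**Figure D4:**
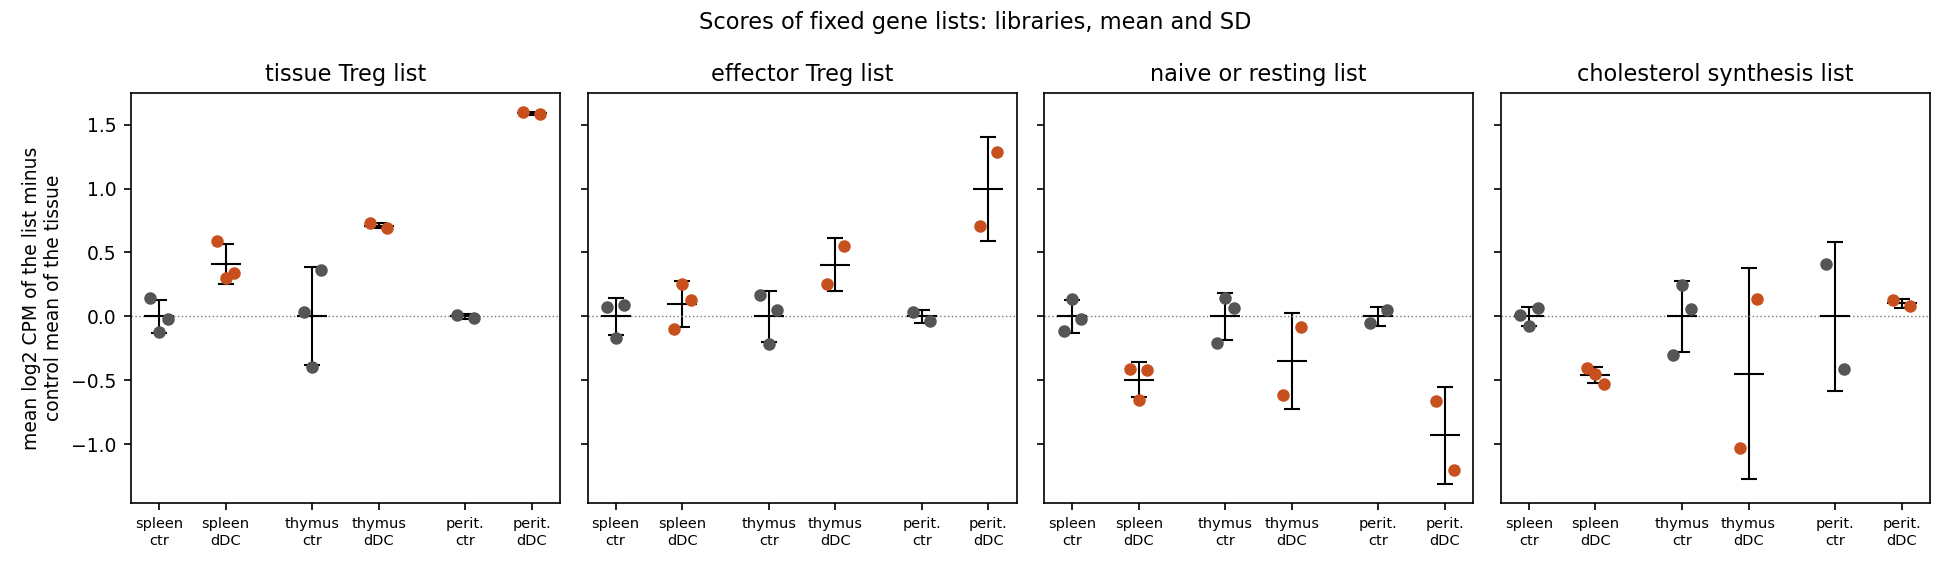
Scores of 4 fixed lists, the mean log2 CPM of the members minus the control mean of the tissue, in each library (points) with group mean and SD. The tissue Treg score was above 0 in 7 of 7 dDC libraries and the naive score in 0 of 7.

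In the spleen the same receptors led by p, beside the fat oxidation gene Cpt2 on the higher side and Arhgap15, the surface protein gene Ly6c1 and the cilia gene Ccdc114 on the lower side. No gene passed the threshold. As lists, naive T cell genes and genes of cholesterol synthesis, which supplies membranes of dividing cells, were lower, and tissue Treg genes were higher. None of these 3 lists held when the correlation of members was estimated (adjusted p = 0.229 with an estimated correlation for each). With edgeR 0 genes passed (smallest adjusted p = 0.111), beside 786 at an unadjusted p under 0.05 where chance gives 921; limma called 5 and DESeq2 32. Values by edgeR were Nrp1 0.73 (adjusted p = 0.111), Itgb1 0.91 (0.255), Cpt2 1.33 (0.693), Arhgap15 -0.98 (0.46), Ly6c1 -1.44 (0.59) and Ccdc114 -7.86 (0.823), the last from 5.38 ± 2.728 to 0.01619 ± 0.02803 CPM. Foxp3 (0.20), Relb (0.10), Il2ra (-0.27), Ikzf2 (-0.01), Klrg1 (0.24) and Gata3 (0.48) did not pass either. Ly6c1 has near-identical copies, so its value is uncertain.

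Of the 28 lists 7 passed in the spleen, 0 with an estimated correlation and 0 with fry; the lowest adjusted p of the others was 0.0886. The naive list moved down (median -0.36, adjusted p = 3.62e-08; adjusted p = 0.229 with an estimated correlation), and Bcl2 (-1.14), Foxp1 (-0.64) and Ly6c1 fell adjusted over the list alone, 3 of 22, against 0 over all genes. The cholesterol list moved down (median -0.39, adjusted p = 0.000691; adjusted p = 0.229 with an estimated correlation), with 1 of 18 members positive and 0 called. The tissue Treg list moved up (median 0.31, adjusted p = 0.00281; adjusted p = 0.229 with an estimated correlation), and Il1rl1 (1.61), Il18r1 (1.11) and Rora (0.90) rose adjusted over the list alone against 0 over all genes. These 3 members became 0 without spleen control 2, 0 without spleen control 3 and 1 without spleen dDC 2. Itgb1 and Ebi3 (1.16) rose adjusted over the effector list alone, a list that did not pass (0.0893), and only 1 of them did without any 1 of the 6 spleen libraries. Markers of other cells moved as well: the erythroid list was lower (median -0.69, adjusted p = 0.00814; adjusted p = 0.637 with an estimated correlation), as were the B cell list (-0.41, 0.036; adjusted p = 0.749 with an estimated correlation) and the stromal list (-2.88, 0.036; adjusted p = 0.637 with an estimated correlation). The macrophage list was higher (0.64, 0.036; adjusted p = 0.749 with an estimated correlation). The erythroid call was lost without spleen control 1 or spleen dDC 2 (up to 0.573), and the B cell call without spleen controls 2 or 3 or dDC 1 or 2 (up to 0.661). The macrophage call was lost without spleen controls 1 or 3 or dDC 1 or 2 (up to 0.173), and the stromal call without spleen control 2 or dDC 1, 2 or 3 (up to 0.575).

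In the thymus, where Tregs mature and to which older Tregs return, Itgb1 and Fam129a led by p together with Ctsh, which encodes a lysosomal protease. Lower by value were Manea, for an enzyme of sugar chain trimming, Rhoq, for a small GTPase, and Auh, for an enzyme of leucine breakdown. No gene passed the threshold. As lists, tissue Treg, effector Treg and interferon-stimulated genes were higher and naive genes lower. None of them held with an estimated correlation (adjusted p = 0.0739, 0.295, 0.733 and 0.733). With fry only the tissue Treg list passed (adjusted p = 0.0447). Without thymus dDC 2 the interferon list turned down. With edgeR 0 genes passed (smallest adjusted p = 0.107), beside 1211 at an unadjusted p under 0.05 where chance gives 921; limma called 0 and DESeq2 153. The count was 1 without thymus dDC 1 and 56 without thymus dDC 2. Values by edgeR were Itgb1 1.17 (adjusted p = 0.107), Fam129a 0.93 (0.178), Ctsh 6.68 (0.129), Manea -4.05 (0.202), Rhoq -4.29 (0.264, with an overlapping gene) and Auh -2.30 (0.416). Il1rl1 (1.33), Klrg1 (0.68), Nrp1 (0.41), Foxp3 (-0.03), Relb (0.14) and Gata3 (-0.05) did not pass. Pparg, a transcription factor of fat tissue Tregs, was listed at 0 in controls and at 7.374 ± 1.443 CPM in dDC, at least 44-fold higher (adjusted p = 0.746).

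Of the 28 lists 4 passed in the thymus, 0 with an estimated correlation and 1 with fry; the lowest adjusted p of the others was 0.0852. The tissue Treg list moved up (median 0.47, 16 of 22 positive, adjusted p = 6.17e-05; adjusted p = 0.0739 with an estimated correlation) with 0 members called. The effector list moved up (median 0.32, adjusted p = 9.56e-05; adjusted p = 0.295 with an estimated correlation), and 1 member, Itgb1, rose adjusted over the list alone against 0 over all genes. The interferon list moved up (median 0.29, 27 of 32 positive, adjusted p = 0.00107; adjusted p = 0.733 with an estimated correlation) with 0 members called, and without thymus dDC 2 its direction was down (0.958). The naive list moved down (median -0.23, adjusted p = 0.0278; adjusted p = 0.733 with an estimated correlation) with 0 called, and was lost without thymus control 2, control 3 or dDC 1 (up to 0.675). Of other cells, the erythroid list did not pass (0.356), though 4 of its 8 members fell adjusted over the list alone against 0 over all genes; globins have near-identical copies.

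In the peritoneal cavity, dDC Tregs showed shifts of whole lists: genes of tissue and effector Tregs, of Treg identity and of chemokine receptors were higher, and naive genes were lower. By p the inhibitory receptor gene Cd200r1 and the costimulatory receptor gene Tnfrsf4 led on the higher side, and Gtf2i, Actn1 and the Treg receptor gene Gpr83 on the lower side. The only gene to pass with edgeR was Krt83 (ENSMUSG00000067613, chromosome 15, 101485131 to 101491512), higher in dDC at 5.187 ± 3.113 CPM against no count in both controls, at least 30-fold (adjusted p = 0.0214). It belongs to a keratin family with near-identical copies, and its call was lost without peritoneal control 2 (0.161) or peritoneal dDC 2 (0.0654). Genes at an unadjusted p under 0.05 numbered 1171 where chance gives 921; limma called 0 and DESeq2 194. The count was 154 without peritoneal control 1 and 0 without peritoneal dDC 2, and without peritoneal control 2 it was 1, a different gene. Values that did not pass, each with an edgeR adjusted p of 0.104, were Cd200r1 1.90, Tnfrsf4 1.10, Klrg1 1.99, Ccr8 4.53, Itgb1 1.02, Nrp1 0.72, Gtf2i -1.38, Actn1 -1.67 and Gpr83 -3.01. Klrg1 went from 76.71 ± 9.126 to 305.7 ± 13.46 CPM. Il1rl1 (1.57), Gata3 (1.11), Ikzf2 (0.47), Foxp3 (-0.32), Il2ra (-0.27) and Relb (-0.65) did not pass.

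Of the 28 lists 9 passed in the peritoneal cavity, 5 with an estimated correlation and 7 with fry; the lowest adjusted p of the others was 0.0694. In each of them 0 members passed over all genes. The tissue Treg list moved up (median 1.08, adjusted p = 1.25e-11; adjusted p = 0.00586 with an estimated correlation), and 7 of 22 rose adjusted over the list alone, such as Klrg1, Gata3, Rora (0.75) and Batf (0.86). The 7 became 4 without peritoneal control 2 and 2 without peritoneal dDC 2. The effector list moved up (median 0.88, adjusted p = 2.96e-09; adjusted p = 0.0287 with an estimated correlation), and 10 of 28 rose adjusted over the list alone, such as Icos (0.88), Pdcd1 (1.26) and Id2 (1.23), which became 2 and 5 without the same libraries. The naive list moved down (median -0.82, adjusted p = 1.82e-14; adjusted p = 0.0347 with an estimated correlation), and 12 of 22 fell adjusted over the list alone, such as Bach2 (-1.12) and Satb1 (-1.97), while Il7r (0.61) rose. The 12 became 5 and 4 without these libraries. The Treg identity list moved up (median 0.47, adjusted p = 2.76e-06; adjusted p = 0.0347 with an estimated correlation), and 9 of 22 rose adjusted over the list alone, such as Ctla4 (0.48), Ikzf2, Tigit (1.14) and Tnfrsf18 (0.70), while Gpr83 fell. The chemokine receptor list moved up (median 0.73, adjusted p = 6.56e-05; adjusted p = 0.0287 with an estimated correlation), and 6 of 20 rose adjusted over the list alone, such as Cxcr6 (1.59) and Cxcr4 (1.40), while Ccr7 (-0.86) fell. The 6 became 1 without peritoneal control 2, dDC 1 or dDC 2.

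The other 4 peritoneal lists did not hold with an estimated correlation. With fry, type 2 helper genes (adjusted p = 0.00815) and thymic epithelial genes (adjusted p = 0.0352) passed. Type 2 helper genes were higher (adjusted p = 0.0162; adjusted p = 0.0697 with an estimated correlation), with 4 of 10 up and 1, Ecm1 (-0.72), down adjusted over the list alone. The 4 became 1 without peritoneal control 2, 2 without dDC 1 and 2 without dDC 2. Cell cycle genes were higher (adjusted p = 0.0162; adjusted p = 0.31 with an estimated correlation) with 0 called, and the call was lost without peritoneal control 2 (0.208). Mitochondrially encoded mRNAs were lower (median -0.22, adjusted p = 0.000698; adjusted p = 0.31 with an estimated correlation), with 1 of 13 down adjusted over the list alone. Of markers of other cells, the thymic epithelial list of 5 genes was higher (adjusted p = 0.0166; adjusted p = 0.108 with an estimated correlation), with 1 up adjusted over the list alone, Epcam, and was lost without peritoneal control 1 or dDC 2 (up to 0.117). The macrophage list (median -1.95, 2 of 20 positive, adjusted p = 0.997) and the dendritic cell list (median -1.35, 4 of 13 positive, adjusted p = 0.0694) did not pass. The mean of the macrophage list was 25.54 and 148.41 CPM in peritoneal controls 1 and 2, and 40 and 52.46 CPM in peritoneal dDC 1 and 2. With 2 libraries per group the exact permutation cannot give a p under 0.333.

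No gene was shown to respond to the genotype differently between tissues. The test of the difference over the 3 tissues called 0 genes with edgeR (smallest adjusted p = 0.276), beside 885 at an unadjusted p under 0.05 where chance gives 921; limma called 0 and DESeq2 56. The count was 16 without peritoneal control 1 and 8 without thymus dDC 2. The single contrasts with spleen called 0 genes for the peritoneal cavity (900 at an unadjusted p under 0.05) and 0 for the thymus (932) with edgeR. No gene was called in 2 tissues, so overlap was counted at an unadjusted p under 0.01. Itgb1, Nrp1, Fam129a, S100a11, Sh3bgrl and Gm12854 were among the higher genes of all 3 tissues. Higher genes shared by 2 tissues numbered 7 for spleen and thymus (0.33 by chance), 8 for spleen and peritoneal cavity (0.6) and 13 for thymus and peritoneal cavity (1.3), and lower genes 4 (0.48), 9 (0.35) and 4 (0.55). Fold changes of 9044 genes at 10 CPM or more correlated weakly: r was 0.124 for spleen and thymus (exact p = 0.03, adjusted 0.05), 0.166 for spleen and peritoneal cavity (exact p = 0.0333, adjusted 0.05) and 0.121 for thymus and peritoneal cavity (exact p = 0.0667), with a mean of 0.137 (exact p = 0.00167).

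In controls, libraries of peritoneal Tregs held more RNA of Ecm1, a matrix protein gene, and Ifngr1, the interferon gamma receptor gene, than those of spleen Tregs. They also held more of the survival kinase gene Pim1 and of Ptafr, the receptor gene for platelet-activating factor. They held less of the chemokine receptor gene Ccr8, of the decoy receptor gene Il1r2, of the costimulatory receptor gene Tnfrsf9 and of the transcription factor gene Myb. By median log2 value, B cell markers (1.42) and macrophage markers (1.94) were higher in peritoneal controls too, while erythroid and natural killer cell markers were lower. Whether RNA of other cells adds to the genes named here was not tested. Interferon-stimulated, follicular and cell cycle genes were lower as lists. None of these 3 held with an estimated correlation (adjusted p = 0.13 for each). All 3 passed with fry (adjusted p = 0.0205, 0.00741 and 0.0245). With edgeR 146 genes passed, 54 higher and 92 lower, beside 1952 at an unadjusted p under 0.05 where chance gives 921; limma called 51, of which 68.6 percent were higher, and DESeq2 775. Ecm1 rose by 1.96 on the log2 scale (adjusted p = 7.38e-05), Ifngr1 by 2.72 (0.000192), from 389.2 ± 55.48 to 2570 ± 731.8 CPM, Pim1 by 1.81 (0.00332) and Ptafr by 4.77 (0.00936). Lower were Tnfrsf9 (-2.48, 0.00717), Il1r2 (-3.31, 0.0063), Myb (-7.19, 0.00049) and Ccr8 (-7.94, 0.000673), the last from 67.4 ± 6.474 to 0.2446 ± 0.3459 CPM. Krt83 was at least 31-fold lower, Map2 at least 80-fold and Apol9b at least 123-fold, each with no count in peritoneal controls. These 11 genes passed with each of the 5 libraries left out. A fit of the compared groups alone called 1 gene in place of 146, so at most 1 of these 11 passed there. Il1rl1 (2.83, 0.0351), Lmna (3.22, 0.0066), Fosl2 (2.99, 0.0398), Zbtb32 (5.07, 0.0427) and Bhlhe41 (4.96, 0.00717) were higher too, and the last 2 are also known from B-1 cells. Of 45 named genes that passed, 13 and 33 were lost without peritoneal controls 1 and 2, and 20, 17 and 16 without spleen controls 1, 2 and 3. The count of 146 became 336 and 37, and 65, 72 and 72, without the same libraries. Krt83 and Ccr8 rest on the same 2 peritoneal control libraries here and in the comparison of dDC with control.

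Of the 28 lists 7 passed between peritoneal cavity and spleen, 0 of them with an estimated correlation and 4 with fry; the lowest adjusted p of the others was 0.0719. Interferon-stimulated genes were lower (median -1.57, adjusted p = 3.34e-13; adjusted p = 0.13 with an estimated correlation), with 19 of 32 down adjusted over the list alone, such as Isg15 (-2.62), and 7 over all genes. Follicular T cell genes were lower (median -1.43, adjusted p = 5.98e-07; adjusted p = 0.13 with an estimated correlation), with 6 of 11 down adjusted over the list alone, such as Bcl6 (-2.42) and Tox (-1.43), and 3 over all genes. Cell cycle genes were lower (median -0.89, adjusted p = 5.98e-07; adjusted p = 0.13 with an estimated correlation), with 9 of 36 down adjusted over the list alone and 0 over all genes. In the Treg identity list (median -0.37, adjusted p = 0.000155; adjusted p = 0.13 with an estimated correlation) 11 fell and 3 rose adjusted over the list alone, and 5 fell and 2 rose over all genes; Itgae fell (-3.35) and Socs2 rose (2.24). Among other cells, B cell markers were higher (median 1.42, adjusted p = 1.63e-06, and 0.453 with an estimated correlation), with 2 of 15 up adjusted over the list alone and 0 over all genes. Macrophage markers (median 1.94, 16 of 20 positive, camera adjusted p = 0.655) and dendritic cell markers (median 2.8, 9 of 13 positive, camera adjusted p = 0.0793) did not pass. Erythroid markers were lower (adjusted p = 1.02e-06; adjusted p = 0.273 with an estimated correlation), with 8 of 8 down adjusted over the list alone and 1 over all genes. Natural killer cell markers were lower (adjusted p = 0.0197; adjusted p = 0.273 with an estimated correlation), with 2 down adjusted over the list alone and 0 over all genes, and turned up without peritoneal control 1 (0.82).

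Thymic Tregs of controls carried more of the costimulatory receptor genes Tnfrsf4 and Tnfrsf18, of Ecm1, of the interleukin 2 signalling gene Stat5a and of the interferon regulator gene Irf7 than spleen Tregs. They carried less Ly6c1 and less Gpr183, a receptor for oxysterols that guides cells to follicle borders. Of the 82 lower genes 12 are in the B cell list, such as Cd22 and Fcer2a. All 15 tested members of that list fell adjusted over the list alone. The list was lower with camera at the preset correlation (adjusted p = 8.73e-17) and with fry (adjusted p = 0.0129). It did not pass with camera at an estimated correlation (adjusted p = 0.074). With edgeR 111 genes passed, 29 higher and 82 lower, beside 1804 at an unadjusted p under 0.05 where chance gives 921; limma called 101 and DESeq2 588. Tnfrsf4 rose by 1.18 on the log2 scale (adjusted p = 0.00207), Tnfrsf18 by 0.88 (0.00559), Ecm1 by 1.30 (0.00103), Znrf1 by 2.04 (0.00207), Stat5a by 1.19 (0.00559) and Irf7 by 1.17 (0.00655), the last 2 with an overlapping gene. Gpr183 was 2.82-fold lower (0.00528). On the log2 scale Ly6c1 was at -2.51 (0.00156), Fcer2a at -9.77 (0.0026), Siglecg at -9.83 (0.000876) and Cd22 at -10.82 (0.000876), the last from 78.62 ± 39.83 to 0.03642 ± 0.03154 CPM. Ly86 was at least 120-fold and Lilra6 at least 38-fold lower, with no count in thymus. These genes and Fcrla passed with each of the 6 libraries left out. Of 33 named genes that passed, 12, 13 and 15 were lost without spleen controls 1, 2 and 3, and 15, 16 and 18 without thymus controls 1, 2 and 3. The count of 111 became 73 without spleen control 2 and 59, 62 and 45 without thymus controls 1, 2 and 3.

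Of the 28 lists 16 passed between thymus and spleen, 2 with an estimated correlation and 10 with fry; the lowest adjusted p of the others was 0.0743. Treg identity genes were higher (median 0.45, adjusted p = 6.47e-09; adjusted p = 0.0337 with an estimated correlation), with 14 of 22 up and 2 down adjusted over the list alone and 3 up over all genes, such as Ikzf4 (1.24). Cholesterol genes were lower (median -0.79, 0 of 18 positive, adjusted p = 3.18e-09; adjusted p = 0.0337 with an estimated correlation). Immediate-early genes (adjusted p = 2.62e-07; adjusted p = 0.074 with an estimated correlation; 2 up adjusted over the list alone, 0 over all genes), interferon genes (2.47e-05; adjusted p = 0.257 with an estimated correlation; 2 and 1) and NF-kappaB genes (4.2e-05; adjusted p = 0.0715 with an estimated correlation; 1, Rel, and 0) were higher. Genes of interleukin 2 and STAT5 were higher (0.00193; adjusted p = 0.0711 with an estimated correlation), with 6 up and 1 down adjusted over the list alone and 2 up over all genes. Tissue Treg genes were higher by the test and the median of 0.55 (0.0079; adjusted p = 0.123 with an estimated correlation), while the mean was -0.28, with 6 up and 1 down adjusted over the list alone and 1 up over all genes. Type 2 helper genes were higher (median 0.47, mean 0.00, adjusted p = 0.0368; adjusted p = 0.122 with an estimated correlation), with 2 and 1 up, and were lost without spleen control 1, 2 or 3 (up to 0.0705).

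Follicular genes were lower in the thymus (adjusted p = 0.0079; adjusted p = 0.19 with an estimated correlation), with 1 up, Cd200, and 1 down, Cxcr5, adjusted over the list alone and 0 over all genes, and were lost without spleen control 3 (0.0952). Cell cycle genes were lower (0.0247; adjusted p = 0.317 with an estimated correlation) with 0 called, and were lost without spleen control 3 or thymus control 1 or 3 (up to 0.363). Mitochondrially encoded mRNAs were higher (0.0328; adjusted p = 0.452 with an estimated correlation) with 0 called, and were lost without spleen control 1 or 2 or thymus control 2 or 3 (up to 0.117). Markers of other cells moved strongly. B cell genes were lower (median -5.57, adjusted p = 8.73e-17; adjusted p = 0.074 with an estimated correlation), with 15 of 15 down adjusted over the list alone and 12 over all genes. Erythroid genes (4.89e-10; adjusted p = 0.0813 with an estimated correlation; 8 down adjusted over the list alone and 1 over all genes), macrophage genes (1.88e-05; adjusted p = 0.279 with an estimated correlation; 2 and 1) and natural killer cell genes (1.88e-05; adjusted p = 0.0506 with an estimated correlation; 6 and 1, with 1 up over the list alone) were lower. Developing thymocyte genes were higher (0.0359; adjusted p = 0.279 with an estimated correlation), with 1 up adjusted over the list alone and 0 over all genes, and were lost without spleen control 1 or 3 or thymus control 2 (up to 0.401).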

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

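The tests of the difference between tissues for lists and the count of spike-in reads were planned, while the exact permutation of list scores, the average of spleen and thymus and the lists with libraries left out were chosen only after results were seen. For 9 lists the dDC effect in the peritoneal cavity differed from that in the spleen by camera with the preset correlation, with adjusted p between 0.000278 and 0.0367. The median difference on the log2 scale was 0.43 for Treg identity, 0.57 for tissue Treg, 0.58 for effector Treg, -0.38 for naive T cell, 0.32 for cell cycle, 0.62 for chemokine receptor (0.59 at the floor), 0.35 for cholesterol, -0.32 for mitochondrially encoded and 3.79 for thymic epithelial genes (2.47 at the floor). None of the 9 held with an estimated correlation, where adjusted p lay between 0.142 and 0.591. The peritoneal side rests on 2 libraries per group, and no single gene passed the test of the difference with edgeR, where 885 genes had an unadjusted p under 0.05, limma called 0 and DESeq2 56.

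A few reads fell on spike-in sequences, which the comparisons do not use: 6 in spleen dDC 1, 5 in thymus control 2, 4 in thymus control 3, 5 in thymus dDC 1 and 5 in thymus dDC 2, above the limit of 3 that a count of 0 allows. They are too few to scale libraries by, and their origin was not tested.

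Naive genes were lower and tissue Treg genes higher in dDC over the tissues. Chance in the genotype labels was argued against by exact permutation, with the larger p of the 2 scores at 0.0025 (0.0233 adjusted over the lists), provided that the tissues did not share mice. The 2 lists had led the set tests on these same libraries, so the unadjusted p alone is too favourable. RNA of other cells in peritoneal control 2 was tested by leaving that library out. The larger camera adjusted p was then 5.06e-11 with the preset correlation. This p alone cannot decide, since camera with an estimated correlation, at 0.0465 for the naive list with all libraries, was not run there. The list scores, set against the control mean of the tissue, argued against that explanation. Peritoneal controls 1 and 2 lay at 0.014 and -0.014 for tissue Treg and at -0.053 and 0.053 for naive genes. Peritoneal dDC 1 and 2 lay at 1.596 and 1.582, and at -0.663 and -1.202. A bias with expression level or gene length was argued against, since random lists matched for both gave medians of -0.09 to 0.12 for the naive list and -0.12 to 0.16 for the tissue Treg list, where the median nearer to them was -0.51. A shift of the sorted cells from naive-like to tissue-like Tregs may be the cause, as a hypothesis drawn from these same data that was not itself tested. A change in the mix of Treg subsets cannot be separated from a change within cells by bulk counts.

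Itgb1 and Nrp1, which led the average, are 180 kb apart on chromosome 8. A linked chromosomal segment, such as DNA of another strain carried along near a modified gene, predicts that their neighbours move too, and the 9 other tested genes within 2e+06 bases had a median of 0.33 against a bound of 0.329 from other places in the genome (percentile 97.51). That exceeds the bound set beforehand only narrowly. Of the 9, Tomm20 (-0.72), Rbm34 (-0.41) and Gm6091 (-0.16) went the other way, 1 had an unadjusted p under 0.05 and the smallest adjusted p was 0.269. A shared segment stays possible and may add to the change, but the neighbours did not all move with it. Shared regulation in the Tregs was not tested and stays open.

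Genes lower in thymus than in spleen controls may come from RNA of B cells in the spleen libraries. Of the 82 lower genes 12 are in the B cell list, and the other 70, of which 19 are antigen receptor segments, had a median correlation of 0.40 with the B cell marker mean within groups over 10 spleen and peritoneal libraries, where matched genes had an upper bound of 0.09, and 30 had r over 0.5. Spleen control 2, at 328.13 CPM, was the highest of the spleen libraries for these markers, and the sort on the Foxp3 reporter would be expected to remove B cells. A difference between Tregs of the 2 organs stays open for the genes that did not follow the markers.

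The count of 14 genes in the average was exceeded or reached by 1 of 50 splits of the libraries within tissues, the real one. The highest of the others called 3. That argues against chance but cannot exclude it, since only 50 splits were drawn and the tissues were treated as independent. With neighbouring library numbers as a block, which leaves fewer residual degrees of freedom, Itgb1 did not pass in the average (edgeR adjusted p = 0.0929). For spleen dDC against control (0 genes by edgeR, 786 at an unadjusted p under 0.05, limma 5, DESeq2 32; highest other split 0, with 10 of 10 splits as large) and for thymus against spleen controls (111 genes; highest other 0, with 1 of 10 as large), 10 splits are too few for a share under 0.05.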

How the results depend on the processing

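Most alternatives were planned, while the average of spleen and thymus, the replicate block and the left-out libraries and permutation for lists were chosen after seeing the data. A term for sex was not run because all libraries were male and the labels give no shared replicate numbers. Library numbers alternate between control and dDC, with gaps, and thymus control 2 (number 13) has no dDC neighbour. The labels do not say whether a library was left out of the series. Neighbours were tried as a replicate block, although nothing in the labels says that they share an animal, litter or day. Their deviations from the group means correlated at -0.004 to 0.076 in 7 pairs, and 5 of 7 dDC libraries correlated best with their own neighbour. This is a weak hint from the data only. In a group of 2 libraries the deviations mirror each other, so the 2 peritoneal pairs hold the same value (0.022) and the pairs are not independent. With this block the counts were 0 for spleen, 0 for thymus, 0 for the peritoneal cavity, 0 for the average and 0 for the difference, with Itgb1 at 1.07 (adjusted p = 0.0929), Nrp1 at 0.60 (0.117) and Fam129a at 0.76 (0.151) in the average. Of the dDC list calls, the block changed only that of the naive list in thymus (0.0513), and members called over the list alone went from 7 to 4 in the peritoneal tissue Treg list and from 2 to 1 in the spleen effector list. Since the block leaves fewer residual degrees of freedom than the main fit, lost calls may also come from lower power. Where leaving out a library leaves a group with 1, that library is assumed to vary like the other groups. The cause of the changes below was not tested. Reported counts are 0 for spleen, 0 for thymus, 1 for peritoneal cavity, 14 for the average and 0 for the difference between tissues (edgeR; 786, 1211, 1171, 1715 and 885 at an unadjusted p under 0.05), 146 for peritoneal cavity against spleen and 111 for thymus against spleen. With DESeq2 they were 32, 153, 194, 384, 56, 775 and 588. In simulated data 37.2 to 56.8 percent of its calls were false. Those data were drawn with dispersions estimated by edgeR, and DESeq2 was not run on the simulated difference between tissues. With limma spleen gave 5, the peritoneal cavity 0 and peritoneal cavity against spleen 51, of which 68.6 percent were higher, and 42.6 percent were higher between thymus and spleen. With no count filter thymus gave 3, the peritoneal cavity 12, the average 39 and the difference 1, and with the stricter filter thymus gave 2 and the average 23. With the compared groups alone the peritoneal cavity gave 0, peritoneal cavity against spleen 1 and thymus against spleen 48. The average of spleen and thymus gave 3, all among the 14: Itgb1, Nrp1 and Fam129a. Leaving out 1 library gave 0 to 0 for spleen, 0 to 56 for thymus, 0 to 154 for the peritoneal cavity, 5 to 123 for the average, 0 to 16 for the difference, 37 to 336 for peritoneal cavity against spleen and 45 to 84 for thymus against spleen. Of 50 list calls 10 passed with an estimated correlation and 29 with fry, which called 30 lists in all. Overlap between tissues was 0 at an adjusted p under 0.1 and 45 at an unadjusted p under 0.01. The 45 adds up the pairs of tissues in both directions, so a gene shared by all tissues counts once per pair.

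No named gene that passed its threshold changed sign, and these passed in 205 of 288 (average), 8 of 13 (peritoneal cavity), 406 of 585 (peritoneal cavity against spleen) and 344 of 461 (thymus against spleen) alternatives. Signs changed for genes that had not passed. In spleen Ikzf2 was 0.00 with no count filter, and 0.03, 0.02 and 0.03 without control 1, control 2 and dDC 3 (range -0.08 to 0.03). In thymus Relb was -0.04 and -0.21 without control 1 and dDC 1 (-0.21 to 0.43), Foxp3 0.12 without control 3 (-0.16 to 0.12), and Gata3 0.29 (-0.50 to 0.29) and Ikzf2 0.07 (-0.26 to 0.07) without dDC 2. In the average of spleen and thymus Ccr8 was -0.15, Pdcd1 -0.01, Ikzf2 -0.05, Foxp3 0.09 and Relb 0.12; in the average Foxp3 was 0.01 and 0.01 without peritoneal control 2 and dDC 2 (-0.12 to 0.01), and Relb 0.00 without peritoneal control 1 (-0.25 to 0.00). Between peritoneal cavity and spleen Gata3 was 0.18 and 0.20 without spleen control 3 and peritoneal control 2 (-0.26 to 0.20), and 0.05 with limma. The interferon list in thymus turned down without dDC 2 (adjusted p 9.16e-11 to 0.958), and the natural killer cell list between peritoneal cavity and spleen turned up without peritoneal control 1 (adjusted p 0.000267 to 0.82).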

Other observations

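The tests in this part had their predictions written before their results were seen. Several genes of known T cell function stood out by value without passing the threshold. In peritoneal dDC Tregs the receptor genes Cd200r1 went from 56.89 ± 11.21 to 212.5 ± 27.77 CPM and Tnfrsf4 from 761.8 ± 223.4 to 1629 ± 37.31 CPM (edgeR adjusted p = 0.104 for both), and Cish, a brake on interleukin 2 signals, went from 88.41 ± 23.43 to 205.2 ± 17.14 CPM (edgeR adjusted p = 0.222). In the thymus Rel, an NF-kappaB subunit, went from 261.6 ± 23.89 to 146.3 ± 29.76 CPM (edgeR adjusted p = 0.746).

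Genes near Relb were looked at because DNA around a modified allele could differ from that of controls. The 46 tested genes within 2e+06 bases had a median absolute average log2 value of 0.28 (percentile 36.36, bound 0.56), which argues against a shift of that whole neighbourhood. The idea that thymic Tregs of dDC mice may move towards the whole peritoneal profile was argued against as well. Genes called higher in peritoneal controls had a median thymus value of 0.22, as predicted and at percentile 100 of matched sets, but the genes called lower had 0.06 (percentile 81.6), where such a shift needs a negative value. A shift of the higher genes alone was left open.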
